A study of Mus musculus with 4 samples.

How the data were processed

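RNA of mouse D3 embryonic stem cells treated with siRNA against Pnpla6 and RNA of control cells was compared on 4 Agilent whole mouse genome arrays with Cy3 and Cy5, 2 arrays at 24 h and 2 at 96 h of differentiation. Per the labels, 200 ng of total RNA was labelled with a low input kit. On replicate 1 of each time the control RNA was in Cy5, and on replicate 2 the RNA of the silenced cells. The labels do not say what the control cells received. The first slide held both 24 h arrays and 96 h replicate 1, and the second slide held 96 h replicate 2.

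The authors scanned the arrays and extracted them with Agilent Feature Extraction (10.7.1.1 per the file headers), and the labels name limma without a version. The deposited scanner files hold spot and local background signals as intensity in arbitrary units, processed signals as intensity after background subtraction and dye normalization, log ratios as log10 of Cy5 over Cy3, and a p-value of the log ratio from the error model of a single array. The authors' series table holds log10 ratios of silenced to control cells: its values equal the log ratio of the scanner files, with the sign turned on the arrays with control RNA in Cy5, within 4.97e-06. The deposited p-value per spot was not used in any test, since it covers 1 array.

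The scanner files were read with R 4.3.3 and analysed with limma 3.58.1. Mean signals, named in the plan made before the data were examined, are not in the files, and median spot signals took their place, with the median local background. Background was corrected with normexp and an offset of 50, and log ratios were normalized within each array by loess with control spots at weight 0. Of 45018 spots 1639 were controls. Spots flagged as non-uniform (1 spot) were left out, spots of the same probe were averaged, and probes had to be well above background in both arrays of at least 1 RNA group, which 28082 of 41174 probes were. For each gene the probe with the highest mean intensity was tested. Gene symbols came from the RefSeq accession of each probe, which named 24375 probes; 16799 without such an accession kept their own identifier. The files refer to another genome build than the reference table, so no coordinates are given.

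For the silencing effects, log2 ratios of silenced to control cells on all 4 arrays were fitted with limma with a mean per time and a term for dye orientation, and a contrast gave the difference between times. Dye orientation and replicate number coincide, so this term is also a block on the replicate number. The fit leaves 1 residual degree of freedom per gene, so that the p-values lean on the spread shared over genes (33.1 prior degrees of freedom). For the control cells at 96 h against 24 h, single channels were fitted with lmscFit after Aquantile normalization, with a dye term and an intraspot correlation of 0.896. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05 over all genes of a comparison; all tests were two-sided. No test across groups of at least 3 arrays was possible, so other groupings of the arrays were not counted.

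Before the data were examined, 22 gene lists with 620 genes were fixed, of which 592 genes were on the array and 504 were tested. They cover pluripotency, the 2-cell-like state, the epiblast and primitive streak, endoderm, mesoderm and cardiac muscle, neural genes, blood vessel and blood, lung and airway, extraembryonic tissue and trophoblast, feeder fibroblast markers, extracellular matrix and adhesion, BMP, Wnt and TGF-beta targets, phospholipid and choline metabolism, cholesterol synthesis, endoplasmic reticulum stress and the amino acid response, heat shock, hypoxia and glycolysis, p53 targets and apoptosis, the cell cycle, the mitochondrial respiratory chain, the interferon response and immediate early genes. They were tested with limma's camera with a preset correlation of 0.01 and, for the silencing effects but not the control time course, with an estimated one; adjusted p-values are over the 22 lists. With an estimated correlation no list passed, and neither did a list of 28 genes shifted by 0.15 in simulated data (adjusted p = 0.927), which the preset correlation found (adjusted p = 1.5e-22). So the estimate from 1 residual degree of freedom had little power there. The simulated genes varied independently, so they do not show how the preset correlation fares with correlated genes. Without the dye term, which leaves 2 residual degrees of freedom, no list passed with an estimated correlation either. The lowest camera adjusted p was then 0.547 at 24 h, 0.277 at 96 h and 0.344 for the difference.

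Named genes followed a rule fixed at the same time: Pnpla6; in each comparison the 12 genes with the largest rise and the 12 with the largest fall among those that passed with the same sign on both arrays and have a plain symbol; and up to 4 members of each list past the threshold, or up to 2 with the smallest p where none passed. Not every gene that the rule selects is printed. Genes of the 2 lists added later were named after their values were seen.

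The fit was tested on simulated data with 21754 genes, of which 200 were changed at each time and 200 in the control time course. It found 73.1% of the 1.2-fold changes at 24 h and 82.1% at 96 h, and 100% of the 1.5-fold and 2-fold changes at both. Among 197 and 211 calls there, 15 and 23 were false, more than the nominal share. For the difference 33.3%, 99.3% and 100% of the 1.2-, 1.5- and 2-fold changes were found, with 33 false among 342 calls. Without the dye term 0%, 20.9% and 92.4% were found at 96 h, with 0 false among 75 calls, and in the control time course 0%, 29.9% and 84.8%, with 0 false among 76.

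Each result was recomputed with other background corrections, with Agilent's processed signals, with median centring, with the authors' ratios, with other filters, with every probe tested on its own, without the dye term, with only the arrays of the time compared and without each array in turn. In the fits of silencing effects to 2 or 3 arrays the dye term was left out too, since it would leave no residual degree of freedom. The control time course was also run with other normalizations between arrays. Added after the data were seen were a prior with an intensity trend and robust estimation, leaving out spots flagged as population outliers (96 to 118 per array), and counting only genes with the same sign on both arrays.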

Results

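The data came from 4 mouse whole-genome oligonucleotide arrays read in Cy3 and Cy5. Each carried RNA of D3 embryonic stem cells treated with siRNA against Pnpla6, called silenced cells at both times, beside RNA of control cells. Pnpla6 encodes neuropathy target esterase, a phospholipase of the endoplasmic reticulum that degrades phosphatidylcholine. The cells were differentiating as embryoid bodies without LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated, and RNA was taken after 24 h and after 96 h. There were 2 arrays per time, and the dyes were exchanged between them. Each array held 43379 spots other than controls, of which 62.5% to 68.7% per channel were well above background. Median spot intensity was 55 to 63 in Cy3 over a local background of 19 to 22, and 114 to 130 in Cy5 over 58 to 64. No spot was saturated. After filtering, 21754 genes or transcripts were tested, 13134 of them with a gene symbol. The number of arrays, 2 per time, limits the precision. The labels do not say whether the 2 arrays of a time came from separate cultures or from the same extracts. So the spread behind the p-values may be technical alone. For the silencing effects it is what remains after the dye term, which also takes out a replicate difference shared by both times. It leans mostly on the spread shared over genes, not on how far the 2 arrays of a time differ for a gene.

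The first question was how far Pnpla6 itself was lowered. At 24 h its log2 ratio of silenced to control cells was −0.87 (SE 0.06, n = 2 arrays, limma adjusted p = 2.7e-11), with −0.73 on replicate 1 and −1.002 on replicate 2, which left 54.9% of the control level. The second Pnpla6 probe, which was dimmer and not used in the test, gave −0.57, or 67.5% of the control level. At 96 h the same ratio was 0.01 (SE 0.06, n = 2 arrays, limma adjusted p = 0.960), with 0.12 and −0.11 on the 2 arrays, and the second probe also gave 0.01. The difference between the times was 0.87 (SE 0.09, limma adjusted p = 6.6e-09). Leaving out either 24 h array left the direction, at −1.002 and −0.73, but the 24 h call was lost there and with the authors' own ratios (−0.92, limma adjusted p = 0.621). Without the dye term, which is also the replicate block, the 24 h ratio stayed at −0.87 with a limma adjusted p of 1.00.

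**Figure D1:**
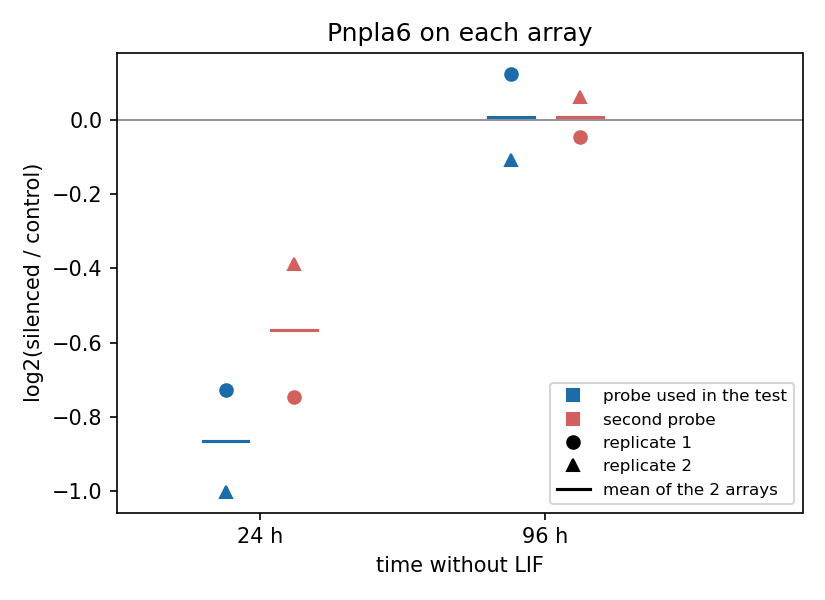
Log2 ratio of silenced to control cells for the 2 Pnpla6 probes on each of the 4 arrays, by hours without LIF. Points are single arrays and bars are means of 2 arrays. The probe used in the test lies at −0.73 and −1.002 at 24 h and at 0.12 and −0.11 at 96 h.

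The next comparison asked which other transcripts differed between silenced and control cells at 24 h, when Pnpla6 was low. Pnpla6 had the largest fall of all. Among the named genes, Otud6b, which encodes a deubiquitinase, fell by 0.39 on the log2 scale, and Atf3, a transcription factor induced by stress, fell by 0.31. Ankrd24 rose by 0.36, Bmerb1 by 0.33, the poly-ADP-ribosylating enzyme Tnks by 0.32 and Spryd3 by 0.30. Each of these values has an SE of 0.06 and the same sign on both arrays. Among 21754 genes tested, 81 changed in limma, 51 higher and 30 lower, and 63 of the 81 had the same sign on both arrays. Of the 81, 4 differed by 1.5-fold or more, 3 higher and 1 lower.

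Before the dye term was fitted, several of the largest rises at 24 h lay on replicate 1 alone. Such ratios of single arrays still hold the dye bias. Plekha5 gave 0.73 on replicate 1 and 0.01 on replicate 2, Ltb 0.61 and 0.01, Kdm5b, a histone demethylase, 0.60 and 0.01, Ap3b2 0.57 and 0.02, Brwd1 0.56 and 0.03, and the linker histone H1f5 0.55 and 0.03. The rises of Fn3k (0.31) and Rab5c (0.30) were spread over both arrays. Falls that lay mainly on replicate 1 were Aatk (−0.61 and −0.08) and Washc2 (−0.52 and −0.04). Further falls were Kcnmb2 (−0.37), Zcchc13 (−0.35), Inip (−0.35), Mgat2 (−0.28), Spryd4 (−0.28) and Dpy19l3 (−0.28). Other probes gave −0.01 for Inip, 0.00 for Plekha5, 0.03 for Kdm5b, −0.01 to 0.06 for Brwd1, 0.11 for Bmerb1, 0.17 for Tnks and −0.21 for Otud6b. Pou5f1, the pluripotency factor Oct4, passed the test at 0.68 (SE 0.07). Its arrays gave 1.58 and −0.21 before the dye term was fitted, so its direction at 24 h was not shared by these ratios.

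Of the 22 gene lists fixed before the data were examined, 5 were shifted at 24 h in limma's camera test, all by small amounts. Immediate early genes were lower: 17 of 18 measured members had a negative ratio and the median was −0.05, but only Atf3 passed on its own (adjusted p = 0.0022; adjusted over the list alone, also 1 gene). Pluripotency genes were higher (adjusted p = 0.0057), with a median of 0.03 over 28 members, 20 of them positive. There Pou5f1 was the only member past the threshold, and 3 were higher when adjusted over the list alone. The list for endoplasmic reticulum stress and the amino acid response was lower (median −0.02, 28 members, adjusted p = 0.014), with Atf3 its only member past the threshold and 2 lower adjusted over the list alone. The list named for targets of BMP, Wnt and TGF-beta was higher (median 0.05, 21 members, camera adjusted p = 0.021). The list of p53 targets and apoptosis genes was lower (median −0.04, 30 members, camera adjusted p = 0.021). No member of either list was past the threshold over all genes. With an estimated correlation, where the test had little power in simulated data, the camera adjusted p was 0.876 for all 5 lists.

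The remaining 17 lists did not pass at 24 h, with adjusted p-values from 0.090 for heat shock to 0.959 for the 2-cell-like state. In them only Nefl of the neural list, a neurofilament gene, passed on its own (0.29, with 0.26 and 0.32 on the 2 arrays). The phospholipid and choline metabolism list, the pathway of Pnpla6, had a median of 0.00 over 39 members and none past the threshold; its smallest p-values belonged to Lpcat2 (0.19) and Pla2g6 (0.16). The cholesterol synthesis, extracellular matrix, trophoblast and mitochondrial lists had medians within 0.01 of 0 and a test direction opposite to the sign of their median or mean. No gene passed at 24 h in limma with an offset of 16, with the authors' ratios, without the replicate block or with any 1 array and the dye term left out, where 1616, 1577, 216 and 193 to 296 genes had an unadjusted p under 0.05. Leaving out 24 h replicate 1 kept none of the 5 list calls, and leaving out 24 h replicate 2 kept 1. Heat shock and mitochondrial genes passed camera without replicate 1, and mitochondrial genes without replicate 2. Each of these fits has 1 array at 24 h and no dye term, so the dye bias stays in its ratios.

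At 96 h, where the Pnpla6 ratio was 0.01, the question was which transcripts differed between silenced and control cells. Cubn, an endocytic receptor of the visceral endoderm, was 2.07-fold higher, and Tgfbi and Sfrp1, a secreted matrix protein and a secreted Wnt antagonist, were 1.84-fold and 1.76-fold higher. The inducible heat shock gene Hspa1a was 2.28-fold higher. Trim55, a muscle RING finger protein, was 2.79-fold lower, the actin-binding smooth muscle gene Tagln 2.37-fold lower, and Nes, the intermediate filament of neural progenitors, 2.03-fold lower.

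Among 21754 genes, 2917 changed at 96 h in limma, 1438 higher and 1479 lower, and 2753 of them had the same sign on both arrays. The larger changes were mostly falls: 119 genes fell and 23 rose by 1.5-fold or more, and 19 fell and 2 rose by 2-fold or more. In log2 units, with an SE of 0.06 to 0.07 from 2 arrays each, the 12 largest named rises were Hspa1a (1.19), Cubn (1.05), Tgfbi (0.88), Sfrp1 (0.82), Crtac1 (0.76), Vax2 (0.72), Aqp8 (0.70), Srgn (0.66), Ly75 (0.63), Acss1 (0.62), Klhdc7a (0.62) and Spp1 (0.62). Among the 12 largest falls were Trim55 (−1.48), Fndc3c1 (−1.42), Pdpk1 (−1.33), Tagln (−1.25), Ddx25 (−1.19), the metal transporter Slc39a8 (−1.17), Anxa3 (−1.15), the kinase Pim2 (−1.03), the imprinted adaptor Grb10 (−1.02), Nes (−1.02) and the integrin Itga1 (−0.98). The limma adjusted p of the 12 rises and 12 falls ran from 8.8e-18 to 4.5e-09. The fall of Pdpk1 was not seen on its 2 other probes, which gave 0.08 and 0.07. Other probes gave smaller values for some: −0.16 for Ddx25, 0.40 for Sfrp1, and −0.35 and −0.21 for Grb10. Those of Hspa1a were 0.73 and 1.22, that of Fndc3c1 −1.10 and those of Pim2 −0.86 and −1.02. Without the replicate block the 12 rises and 12 falls passed except Vax2, Ly75 and Klhdc7a.

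**Figure D2:**
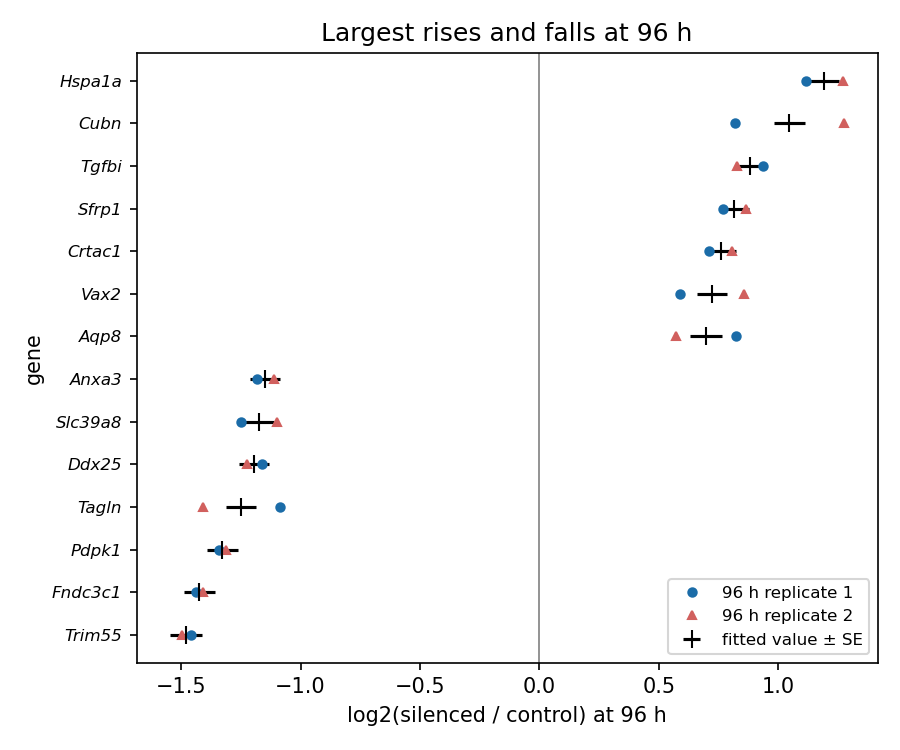
Log2 ratio of silenced to control cells at 96 h for the 7 named genes with the largest rise and the 7 with the largest fall. Circles and triangles are the 2 arrays, and crosses are the fitted value with its SE. Hspa1a lies at 1.11 and 1.27 and Trim55 at −1.46 and −1.50.

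Cholesterol synthesis genes were lower at 96 h: 14 of 22 measured members fell and none rose, and 18 fell adjusted over the list alone; 13 of the 14 falls had the same sign on both arrays. The median was −0.21, and among them were Msmo1 (−0.48), Fdps (−0.45) and Hmgcs1 (−0.39, other probe −0.07). The camera adjusted p was 6.1e-10. Hypoxia and glycolysis genes were higher (adjusted p = 1.1e-06): 11 of 28 rose, 14 adjusted over the list alone, and none fell. The median was 0.15, and Ndrg1 rose by 0.60, the phosphofructokinase gene Pfkp by 0.49 (other probe 0.00), P4ha1 by 0.38 (other probe 0.19) and Ankrd37 by 0.35. Both shifts had an adjusted p of 0.607 with an estimated correlation.

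Pluripotency genes were on balance higher at 96 h and epiblast genes lower. In the pluripotency list 14 of 28 members rose and 3 fell (15 and 4 adjusted over the list alone; 12 of the rises and 2 of the falls had the same sign on both arrays), the median was 0.18, and the adjusted p was 0.00019. Tcl1 rose by 0.52, Lefty2 by 0.39 and the nuclear receptor gene Esrrb by 0.37. Pou5f1 gave −1.05, from 0.01 on replicate 1 and −2.11 on replicate 2, so only 1 array showed a fall before the dye term was fitted. In the list of the epiblast and primitive streak 6 of 15 members fell and none rose (adjusted over the list alone, 6 fell and 2 rose), with a median of −0.04 and an adjusted p of 0.00018. The falls were large: Fgf5 −0.69, the DNA methyltransferase gene Dnmt3b −0.64, Wnt3 −0.64 and Pou3f1 −0.63. Both lists had an adjusted p of 0.607 with an estimated correlation.

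Of the 10 feeder fibroblast markers measured, 5 fell and 1 rose at 96 h, with a median of −0.18 (adjusted over the list alone, 6 and 1; adjusted p = 0.0087). Cxcl12 fell by 0.71, Dcn by 0.44 and Col1a2 by 0.35, and Fbln2 rose by 0.47. In the control cells 9 of these 10 genes were above background on both 24 h arrays, and 2 of the 10 also stand in another list. Interferon response genes were lower (8 of 23 fell, 7 of them with the same sign on both arrays, and 1 rose; adjusted over the list alone, 8 and 2; median −0.04; adjusted p = 0.013), among them Oasl2 (−0.50), Cxcl10 (−0.47) and Irf1 (−0.38, other probe −0.22), and Ifitm1 rose by 0.34. Blood vessel and blood genes were higher (6 of 25 rose, 2 fell; adjusted over the list alone, 7 and 2; median 0.05; adjusted p = 0.044), with Vwf at 0.42 (other probe 0.18), Vegfa at 0.35, Eng at 0.33 and Etv2 at −0.36. With an estimated correlation the adjusted p was 0.706 for the feeder markers and 0.607 for the other lists in this group.

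**Figure D3:**
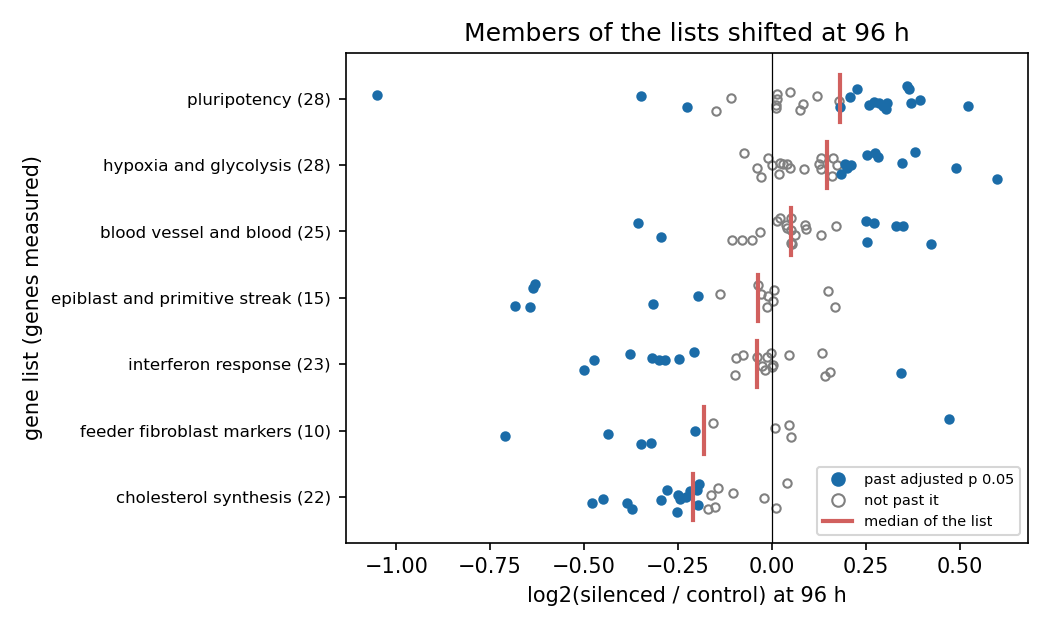
Log2 ratio of silenced to control cells at 96 h for the measured members of the 7 shifted gene lists. Filled points passed the limma test over all genes, open points did not, and bars are list medians. The medians run from −0.21 for cholesterol synthesis to 0.18 for pluripotency genes.

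The other 15 lists did not pass the camera test, and in 13 of them members rose and fell. In the list named for targets of BMP, Wnt and TGF-beta, 3 of 21 members rose and 5 fell (camera adjusted p = 0.073). The falls included the BMP-induced genes Id1 (−0.63), Id3 (−0.60) and Id2 (−0.40, other probe −0.20). The rises were Id4 (0.30), a relative of these genes, and Gli1 (0.21) and Ptch1 (0.18), all 3 named after their values were seen. The name of the list does not hold for all its members, Gli1 and Ptch1 among them. Of 39 phospholipid and choline genes, 7 rose and 4 fell (adjusted p = 0.081), with Pnpla3 at 0.40, Chpt1 at 0.36 (other probe −0.01), Gde1 at 0.30 and Selenoi at −0.31 (other probes −0.05 and −0.24). In the endoderm list 5 of 25 rose and 3 fell (adjusted p = 0.084), with the basement membrane collagens Col4a1 at 0.33 and Col4a2 at 0.30, and Amn at 0.29 beside Cubn. Of 18 immediate early genes, 2 rose and 6 fell (adjusted p = 0.092): Fos rose by 0.44 and Ier3 by 0.41, and Junb gave −0.49 and Jun −0.34. In the matrix and adhesion list 6 of 31 rose and 6 fell (adjusted p = 0.650), with Ccn1 at −0.97, Tgfbi at 0.88, Cldn7 at −0.80 and Ccn2 at −0.72. In the trophoblast list 2 of 18 rose and 4 fell (adjusted p = 0.437), with Krt8 at −0.78, Peg10 at −0.64, Phlda2 at −0.33 and Esx1 at 0.35.

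Of 34 neural genes, 5 rose and 4 fell (adjusted p = 0.650): besides Nes, Nefl fell by 0.87 and Zic2 by 0.40, and Ncam1 rose by 0.56, with 0.06, 0.14 and 0.80 on its other probes. Of 25 mesoderm and heart genes 2 rose and 3 fell (adjusted p = 0.573), with Myl7 at 0.29 and Myl2 at 0.23. In the lung list 5 of 22 rose and 3 fell (adjusted p = 0.697), with Gli3 at −0.63 and Gli2 at 0.38 (other probe 0.24). Of 30 p53 targets and apoptosis genes 3 rose and 4 fell (adjusted p = 0.949), with Bcl2 at −0.61, Perp at −0.41 and Gdf15 at 0.30; only 1 of the 3 rises, that of Gdf15, had the same sign on both arrays. In the list for endoplasmic reticulum stress 3 of 28 rose and 3 fell (adjusted p = 0.273): the serine synthesis genes Phgdh (−0.43) and Psat1 (−0.34) fell, as did Atf3 (−0.25), and Ddit3 rose by 0.31. In the heat shock list only Hspa1a and Hspb1 (0.19) rose and Hspe1 (−0.22) fell among 11 (adjusted p = 0.544). In the cell cycle list 1 of 37 rose and 4 fell (adjusted p = 0.248), with Cdkn1c at −0.25 and Cdkn2a at 0.22. No member changed in the mitochondrial list (25 genes, adjusted p = 0.872) or the 2-cell-like list (4 genes, adjusted p = 0.985). For the heat shock, trophoblast, mesoderm and p53 lists the median or the mean had the sign opposite to the test's direction.

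The 96 h count was 106 without the replicate block (15 higher, 91 lower; among the list members Wnt3, Pou3f1, Cxcl12, Id3, Ccn1, Ccn2, Nefl and Bcl2), 29 to 114 with 1 array left out and no dye term, 1016 with an offset of 16, 1798 with median centring (1126 higher, 672 lower), and 0 in limma with the authors' ratios, where 3853 genes had an unadjusted p under 0.05. Of the 2 arrays of 96 h, replicate 2 was the only one on the second slide, and within the first slide, without it, 36 genes changed, 2 higher and 34 lower. Without 96 h replicate 2 the shifts of interferon response and of blood vessel and blood genes were lost (camera adjusted p = 0.098 for both), and without 96 h replicate 1 those of feeder markers (0.078) and of blood vessel and blood genes (0.197). Without 96 h replicate 2 the lists for endoplasmic reticulum stress (0.038) and for phospholipid and choline metabolism (0.043) passed.

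The effects of silencing at the 2 times were then set against each other. Across the 21754 genes, which are not independent replicates, the log2 effects at 24 h and 96 h had a Pearson correlation of −0.03 and a Spearman correlation of −0.01. In limma's test of the difference itself, 1506 genes passed, 615 with a higher and 891 with a lower effect at 96 h. The largest differences upward were Cubn (1.101), Hspa1a (1.04), Pnpla6 (0.87), Sfrp1 (0.72) and St3gal3 (0.72), and the largest downward were Pou5f1 (−1.74), Trim55 (−1.53), Pdpk1 (−1.35 on the probe tested; its 2 other probes gave 0.08 and 0.07 at 96 h), Fndc3c1 (−1.31) and Tagln (−1.25), each with an SE of 0.09. Both times shared 34 changed genes. Of these 5 had the same direction, 2 higher and 3 lower, where independent lists would share 3.37 and 2.04. The other 29 were opposite, and 26 of them were higher at 24 h and lower at 96 h. No expected number was computed for the opposite directions. Before the dye term was fitted, these 29 had larger ratios on 1 array per time. Their median absolute log2 ratio was 0.45 on 24 h replicate 1 and 0.16 on replicate 2. At 96 h it was 0.21 on replicate 1 and 0.53 on replicate 2. The dyes were exchanged between the arrays of a time, so a dye bias shared by both times stays in these ratios. They do not show that 1 array per time made the calls.

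In camera's test of the difference 9 lists passed. Cholesterol synthesis (median difference −0.23, adjusted p = 2.1e-07), the epiblast and primitive streak (−0.15, adjusted p = 6.2e-05), feeder markers (−0.21), interferon response (−0.058) and BMP, Wnt and TGF-beta targets (−0.053) had lower effects at 96 h than at 24 h. Hypoxia and glycolysis (0.13, adjusted p = 0.00013), pluripotency (0.11), blood vessel and blood (0.10) and endoplasmic reticulum stress (0.093) had higher ones. With an estimated correlation the adjusted p was 0.640 for 8 of these lists and 0.707 for the feeder markers. In the heat shock, immediate early, trophoblast, mesoderm, lung and matrix lists, which did not pass, the median or the mean had the sign opposite to the test's direction. Leaving out 1 array kept the calls of cholesterol synthesis, the epiblast and primitive streak, hypoxia and glycolysis, and BMP, Wnt and TGF-beta targets; those of the other lists were lost without at least 1 of the arrays, with camera adjusted p-values from 0.065 to 0.592. In limma, no gene passed the test of the difference without the replicate block, with any 1 array and the dye term left out or with the authors' ratios, where 1297, 844 to 1084 and 2953 genes had an unadjusted p under 0.05.

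The control channels gave the course of differentiation from 24 h to 96 h. Among the largest rises were the epithelial genes Krt18 (16.3-fold) and Cldn7 (10.2-fold), the trophoblast and germ cell transcription factor Tfap2c (14.3-fold) and Fndc3c1 (18.1-fold). Among the largest falls were Sall3 (10.1-fold), Lgals3 (9.48-fold) and the immediate early gene Egr1 (7.67-fold). The epiblast marker Fgf5 was 6.91-fold higher, and the pluripotency genes Nr0b1 and Klf5 were 3.62-fold and 3.17-fold lower. Pnpla6 fell by 0.34 (SE 0.10, limma adjusted p = 0.031, n = 2 channels per time), and without 96 h replicate 2 its value was −0.27 (limma adjusted p = 0.054). In limma's fit to the single channels 7917 of 21754 genes changed, 4235 higher and 3682 lower, and 858 rose and 387 fell by 2-fold or more. Further large rises were Car4 (3.74), Prtg (3.59), Trim55 (3.29), Pdlim4 (3.22), Pdzk1 (3.11), Crym (3.08) and Rimkla (2.97), in log2 units, and Mogat2, which was not above background at 24 h, was at least 8.13-fold higher. Further falls were Gpr83 (−3.42), Emp1 (−3.15), Crct1 (−3.14), Gsta3 (−3.11), Hopx (−3.05), Fetub (−2.85), Ttn (−2.72) and Accsl (−2.68), and Cabs1, not above background at 96 h, was at least 6.53-fold lower.

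Of the 22 lists 10 were shifted in the control cells. Genes of extraembryonic tissue and trophoblast were on balance higher (10 of 18 rose and 4 fell, camera adjusted p = 9.1e-08), with Rhox9 at 1.89 and Rhox5 at 1.13 besides Krt18 and Tfap2c. The 4 falls, named after their values were seen, were Phlda2 (−1.10), Tead4 (−0.58), Peg3 (−0.50) and Cdx2 (−0.42). Endoderm genes were higher (12 of 25 rose, 1 fell; adjusted p = 0.0019), among them Krt19 (1.83), Cldn6 (1.70), the endocytic receptor gene Lrp2 (1.60) and Dab2 (1.12). Epiblast and primitive streak genes were higher (8 of 15 rose, none fell; adjusted p = 0.0017), with Wnt3 at 1.21, Otx2 at 1.08 and Dnmt3b at 0.78. Pluripotency genes were lower (2 of 28 rose, 10 fell; adjusted p = 0.027), and Dppa3 at 1.99 moved against the list. Matrix and adhesion genes were higher (12 of 31 rose, 4 fell; adjusted p = 0.011), with Mmp2 at 1.61, Cldn3 at 1.35 and the mesenchymal filament gene Vim at −2.61.

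Among lists of cell state, p53 targets and apoptosis genes were higher (18 of 30 rose, 1 fell; adjusted p = 5.3e-06), with Trp53inp1 at 1.65, Bbc3 at 1.60, the cell cycle inhibitor Cdkn1a at 1.42 and Pmaip1 at 1.38. Hypoxia and glycolysis genes were higher (13 of 28 rose and 1 fell, camera adjusted p = 0.0038), led by Bnip3 (1.70) and Aldoc (1.36). The 1 fall was that of Ndrg1 (−0.91). Cell cycle genes were lower (2 of 37 rose, 18 fell; adjusted p = 0.00011), among them Ccne1 (−1.49) and Mcm3 (−0.98). So were cholesterol synthesis genes (none of 22 rose, 16 fell; adjusted p = 5.3e-06), among them Cyp51 (−0.99) and Mvd (−0.94), and heat shock genes (none of 11 rose, 6 fell; adjusted p = 0.00079), among them Hsph1 (−1.59) and Hspa1a (−1.39). Adjusted over the list alone, the counts of these 10 lists differed only for epiblast (9 higher), endoderm (13 higher), p53 (2 lower) and cell cycle genes (3 higher, 24 lower).

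**Figure D4:**
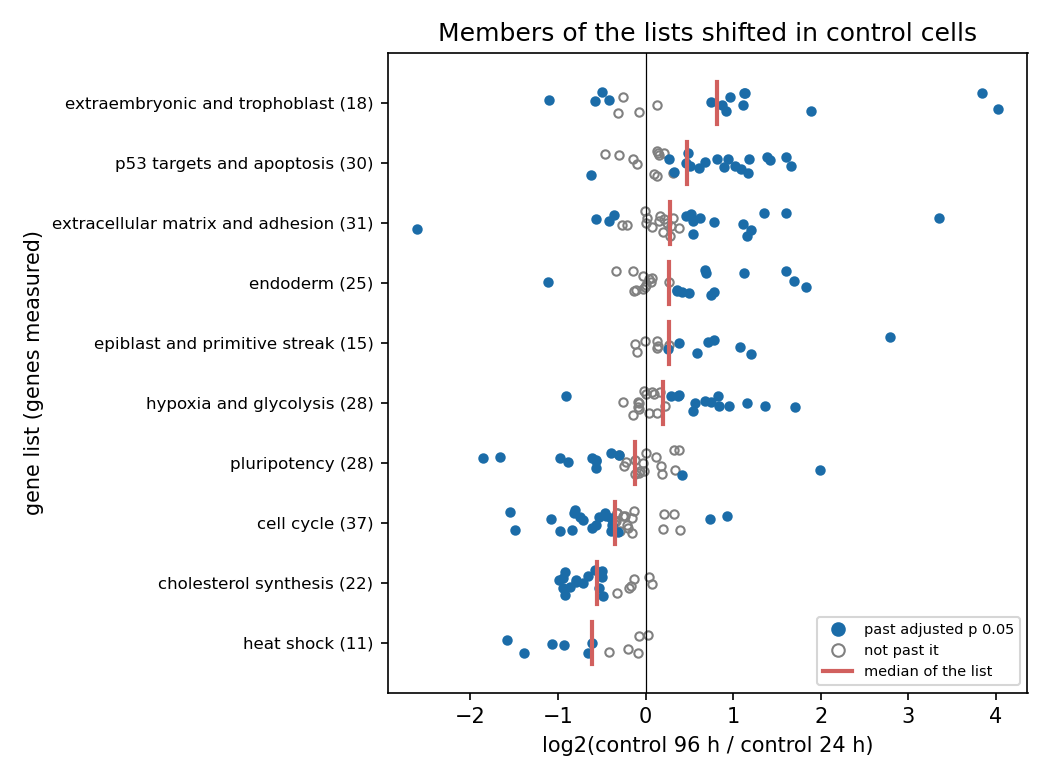
Log2 ratio of control cells at 96 h to control cells at 24 h for the measured members of the 10 shifted gene lists. Filled points passed the limma test over all genes, open points did not, and bars are list medians. The medians run from −0.61 for heat shock genes to 0.81 for genes of extraembryonic tissue and trophoblast.

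The other 12 lists held changes in both directions or none, with camera adjusted p-values from 0.066 for the interferon response to 0.869 for the 2-cell-like state. In the interferon list 9 of 23 rose and 5 fell, with Bst2 at 1.76 and B2m at 1.71. Of the 10 feeder markers 5 rose and 1 fell, with Cxcl12 at 1.83 and Dcn at 1.03. Of 39 phospholipid and choline genes 13 rose and 7 fell, with Lpin1 at 1.34 and Pnpla7, a relative of Pnpla6, at 1.01. Members of the list named for targets of BMP, Wnt and TGF-beta went both ways (6 of 21 rose, 6 fell), with Id3 at −2.12 and Lef1 at −1.76. Immediate early genes did too (4 of 18 rose, 4 fell), with Myc at −1.91, and there the median (0.08) and the test's direction differed in sign. Blood vessel and blood genes (6 rose, 9 fell of 25) included Vegfa (1.35) and Vegfc (−1.60). Neural genes (5 and 5 of 34) included Gbx2 (−2.53) and Hes5 (1.08), and mesoderm and heart genes (3 and 5 of 25) Tagln (2.55) and Bmp4 (−1.64). Lung genes (5 and 5 of 22) included Foxj1 (1.38), mitochondrial genes (1 and 4 of 25) Cycs (−0.55), and the list for endoplasmic reticulum stress (4 and 7 of 28) Ddit4 (2.74). Times were compared between arrays, and on the first slide, without 96 h replicate 2, 10146 genes changed, 5299 higher and 4847 lower. Without normalization between arrays, 4865 were higher and 2771 lower. The fall of pluripotency genes was lost without 24 h replicate 2 (camera adjusted p = 0.066), 96 h replicate 1 (0.085) or 96 h replicate 2 (0.168). The feeder markers passed with any 1 array left out, with camera adjusted p-values from 0.0027 to 0.040, and the interferon response passed without each array except 24 h replicate 1, from 0.016 to 0.042.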

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

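The tests of causes in the next paragraphs were all chosen after the results they weigh had been seen, except the test within ranges of intensity. The gene lists compared in this paragraph were fixed before the data were examined. Each result listed differed between the 24 h and 96 h effects in a test of the difference itself. In limma 1506 genes did so. Pnpla6 differed by 0.87 on the log2 scale. Larger effects at 96 h than at 24 h were found for Cubn (1.101), Hspa1a (1.04), Sfrp1 (0.72), St3gal3 (0.72), Aqp8 (0.71), Tgfbi (0.70), Klk1 (0.70), Inhbb (0.68), Vax2 (0.66), Cyp2s1 (0.65) and Srgn (0.63). Lower ones were found for Pou5f1 (−1.74), Trim55 (−1.53), Pdpk1 (−1.35; 0.08 and 0.07 at 96 h on its 2 other probes), Fndc3c1 (−1.31), Tagln (−1.25), Slc39a8 (−1.19), Ddx25 (−1.18), Nefl (−1.16), Itga1 (−1.09), Plekha5 (−1.06), Anxa3 (−1.06) and Has2 (−1.06). In camera 9 lists differed, with median differences of 0.10 for blood vessel and blood, −0.053 for BMP, Wnt and TGF-beta targets, −0.23 for cholesterol synthesis, 0.093 for endoplasmic reticulum stress, −0.15 for the epiblast and primitive streak, −0.21 for feeder markers, 0.13 for hypoxia and glycolysis, −0.058 for the interferon response and 0.11 for pluripotency. With an estimated correlation none of the 9 passed (adjusted p = 0.640 for 8 of them and 0.707 for feeder markers). For Pou5f1 the arrays of each time disagree before the dye term is fitted (1.58 and −0.21 at 24 h, 0.01 and −2.11 at 96 h). On both replicate numbers, though, its ratio was lower at 96 h than at 24 h. Without the replicate block no gene differed in limma, and 1297 had an unadjusted p under 0.05.

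For 59 of the 81 genes changed at 24 h (72.8%), the fitted dye term pointed to a larger ratio on replicate 1. This was beyond the 31 to 49 of random gene sets of the same size. At 96 h the same term did so for 1512 of the 2917 changed genes (51.8%). The term is shared by the arrays of both times, so these counts cannot show that 24 h replicate 1 differed from the others. A dye bias that differed on that array for part of the genes stays open. Error of single probes as the whole cause is argued against: for the 18 genes with other probes, those probes gave a median of 0.068 in the same direction, just above the −0.015 to 0.051 of unchanged genes, but far below the 0.31 of the changed probes. An effect of the low Pnpla6 level at 24 h stays open, was not tested and cannot be told from another effect of the siRNA treatment.

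The 2917 genes changed at 96 h were weighed against errors of probes, of an array and of labels. The other probes of 722 of them gave a median of 0.136 in the changed direction, and 609 of the 722 had the same direction there. This median lay beyond the 0.024 to 0.037 of unchanged genes, which argues against error of single probes as the whole cause. It lay below the 0.256 of the changed probes themselves. The 2 arrays of 96 h, each freed of dye bias with the 24 h arrays, correlated at 0.398 across genes, where arrays of noise alone gave −0.346 to −0.320 and the 24 h arrays −0.232, which argues against the array on the second slide as the sole source. Exchanged labels on both 96 h arrays cannot be told apart from correct ones, since Pnpla6, the gene that would show it, stood at 0.0081. An effect of the earlier silencing and a difference between the cultures, if each group was a single culture, stay open. The labels do not say what the control cells received, so an effect of Pnpla6 cannot be told from another effect of the siRNA treatment.

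Genes that moved over 2-fold from 24 h to 96 h in the control cells tended to have the opposite silencing effect at 96 h. With the time course and the silencing effect taken from different arrays, the correlation across 1279 genes was −0.269 and in the other pairing, across 1270 genes, −0.295, below the −0.066 to 0.053 of shuffled genes; this argues against measurement error of the shared control channels. The sizes were small: in these pairings the median 96 h effect was −0.040 and −0.053 for genes that rose over 2-fold. For genes that fell over 2-fold it was 0.064 in both. Within ranges of mean intensity the 6 correlations ran from −0.574 to −0.197, which argues against a bias of 1 intensity range. Over all genes the Pearson correlations were −0.078 and −0.109 and the Spearman correlations 0.016 and −0.043. A control culture at 96 h that had moved further than its time, if both arrays shared it, and slower differentiation of the silenced cells stay open.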

How the results depend on the processing

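Of all the alternatives tried, an intensity trend with a robust prior, leaving out population outlier spots and counting only genes with the same sign on both arrays were chosen after the data had been seen. Without the replicate block, which is the dye term, 0 / 106 / 0 genes changed at 24 h, at 96 h and in the difference (216, 2114 and 1297 at an unadjusted p under 0.05 in limma), with a Pnpla6 log2 fold change at 24 h of −0.87 (adjusted p = 1.00); the residual spread then holds the dye bias. The first slide alone, without 96 h replicate 2, gave 36 genes at 96 h. With an offset of 16 the counts were 0 (1616 unadjusted), 1016 (431 higher, 585 lower) and 271 (52 and 219), Pnpla6 gave −0.89 (adjusted p = 0.076) and 1 list was shifted at 24 h. Agilent's processed signals gave 0, 0 and 0 genes (1544, 3794 and 2897 unadjusted), Pnpla6 −0.92 (adjusted p = 0.650), and 1, 4 and 5 lists. The authors' ratios gave 0, 0 and 0 genes (1577, 3853 and 2953 unadjusted), Pnpla6 −0.92 (adjusted p = 0.621), and 1, 4 and 5 lists. Median centring gave 42 (20 higher, 22 lower), 1798 (1126 and 672) and 737 (336 and 401) genes and a correlation of −0.0071 between the times; every probe on its own gave −0.046. Only the arrays of the time compared, also without the dye term, gave 0 (193 unadjusted) and 114 genes and Pnpla6 at −0.87 (adjusted p = 0.339), and the intensity trend gave 51 genes at 24 h. An estimated correlation gave 0, 0 and 0 lists. For these changes the cause was not tested; at 96 h the counts without the dye term were alike with all 4 arrays (106) and with 2 (114). Over these alternatives Pnpla6 kept its sign at 24 h, with limma adjusted p-values from 2.6e-20 to 1.00.

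With each array left out in turn, and no dye term in the silencing effects, the genes changed at 24 h went from 0 to 0 (193 to 296 unadjusted), those at 96 h from 29 to 114, those in the difference from 0 to 0 (844 to 1084 unadjusted), Pnpla6 at 24 h from −1.002 to −0.73, the correlation from −0.026 to −0.0059 and the lists at 24 h from 2 to 5. Pou5f1 reversed: from −0.21 to 1.58 at 24 h and from −2.11 to 0.0065 at 96 h. These end values are the ratios of the 1 array left at that time, with its dye bias. The reversal therefore repeats the disagreement of the single arrays and is no separate test. No other named gene or list reversed in any alternative; 980 of their values lost the threshold and 22 gained it. The control time course stayed between 7290 and 11697 genes, with 4865 higher and 2771 lower without normalization between arrays, which puts the median gene at 0.07. Over all spots the median Cy3 signal was 55 to 63 over a background of 19 to 22; with only probes well above background in all 8 channels, 82, 2795 and 1447 of 19033 genes changed at 24 h, at 96 h and in the difference. Of the 96 genes named at 96 h, 30 passed without the replicate block and 14 to 34 with 1 array left out.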

Other observations

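The lists of imprinted genes and of SRF and YAP target genes were chosen after the 96 h genes had been seen, and leave out the genes that prompted them; the test of a general delay was chosen after the list results were known. Genes of the actin cytoskeleton and cell contact are known targets of the actin-regulated factors SRF and YAP. Falls of Ccn1 (−0.97), Ccn2 (−0.72) and Tagln (−1.25) had raised the question. Of 30 other such genes 9 fell and 2 rose, among them the smooth muscle gene Cnn1 (−0.86), Nt5e (−0.48), Igfbp3 (−0.42), Zyx (−0.36) and the tropomyosins Tpm2 (−0.34) and Tpm1 (−0.28), while Lima1 rose by 0.24 and Nuak2 by 0.20. Their median was −0.083, below the −0.048 to 0.048 of random lists of like intensity, so a fall shared by these targets is a hypothesis, found and tested on the same 2 arrays. The activity of SRF and YAP was not measured. Feeder fibroblast markers moved with these genes at 96 h: 5 of 10 fell and 1 rose, with a median of −0.18, Cxcl12 at −0.71, Dcn at −0.44 and Col1a2 at −0.35. No test separated a change within cells from a change in the share of cells of a fibroblast kind, and both stay open.

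Whether imprinted genes shared a fall stays open. Grb10 (−1.02), Peg10 (−0.64), Phlda2 (−0.33) and Cdkn1c (−0.25) had raised the question. The median of 29 other imprinted genes was 0.019 at 96 h, inside the −0.047 to 0.049 of random lists, which gives no sign of a fall shared by most of them but does not exclude one shared by a few. Of these 29, 2 rose (Cd81 0.28 and Slc38a4 0.20) and 3 fell (Calcr −0.95, Gnas −0.23 and Nnat −0.21), named after their values were seen.

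A delay of the whole course of differentiation in silenced cells would turn every list that shifted with time the opposite way at 96 h. This holds only if each list moved in 1 direction from 24 h to 96 h, which 2 times cannot show. Of the 4 lists shifted both in the control time course and at 96 h, 2 moved the same way (cholesterol synthesis, lower in both, and hypoxia and glycolysis, higher in both) and 2 the opposite way (epiblast and primitive streak, and pluripotency). On that condition, the 2 lists that moved the same way argue against a delay of the whole course. Within the hypoxia and glycolysis list, Ndrg1 moved the opposite way (0.60 at 96 h and −0.91 in the control time course). The 96 h shifts of all 4 lists are lost with an estimated correlation (camera adjusted p = 0.607 for each). So the argument against a delay of the whole course rests on the preset correlation. The estimates were −0.048 for cholesterol synthesis, −0.037 for hypoxia and glycolysis, −0.016 for pluripotency and 0.048 for the epiblast list. They come from 1 residual degree of freedom, and that test had little power in simulated data. The loss therefore does not show that correlated genes made these shifts. A delay of part of the course stays open.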
